A study of Mus musculus with 6 samples.

How the data were processed

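Gene expression was measured by RNA sequencing of total RNA from GL261 cells, per the labels' protocols, in 3 samples of a control line (shNC) and 3 samples of a Pten knockdown line (shPTEN). Groups were taken from the sample titles. The title of the third shNC sample carries the same replicate number as the second, so its number was taken from the prefix of the title. The columns of the deposited table were matched to samples by group and number, and all 6 columns were used. The third shPTEN column carries a library number outside the run of the other 5, and no source used here says whether it marks another batch. Such a batch would hold 1 sample of 1 group, so no value within it can be had, and without that sample 5175 genes were called and the log2 fold change of Pten was -0.5622. The design text names the knockdown line GL262 once, which was read as GL261, the line of every sample label.

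The submitters' processing notes name the build mm10, HISAT2 2.1.0, BWA and HTSeq 0.10.0 without giving their roles. The annotation, the strand setting and the filters are not given in the sources used here. The table deposited by the authors is named for FPKM, but its values are CPM. Every column sums to 1000000 and every value is a whole multiple of the smallest value in its column, whatever the length of the gene. Dividing by that step gave whole reads for 100% of values within 0.01 read, and these recovered reads gave 18372943 to 23573286 reads per sample. CPM is not corrected for gene length, so levels of different genes within a sample are not comparable as molecule numbers, while the same gene can be compared between samples. An HTSeq count leaves out reads that fit several features in its default mode, and whether that mode was used is not given in the sources used here, so overlapping genes, antisense pairs and close paralogs may share or lose reads.

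The table has 27773 rows named by gene symbol, none at 0 in all samples. In it 24 rows carry calendar dates in place of symbols, as a spreadsheet makes from names such as those of the septin genes. They hold at most 0.265% of the CPM of a sample and were left out of all tests, though not out of the sample totals. Gene positions come from GENCODE M21 (GRCm38, the assembly of mm10), matched by symbol, with 27217 of the rows matching and 12326 of the 12468 tested genes having a unique position.

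The design was fixed for FPKM before the data were examined, and its test on a log scale also fits CPM, so test and thresholds were kept. The main test was limma 3.58.1 (R 4.3.3), with lmFit and a 2-sided eBayes test with a mean-variance trend, on log2(CPM + 1) for genes with a mean of at least 1 CPM over the 6 samples, with group as the sole term. P-values were adjusted by the Benjamini-Hochberg method and genes under 0.05 were called. Fold changes are shPTEN minus shNC. For Pten a 2-sided exact permutation test of the mean log2 values was added.

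Gene lists of 30 pathways and cell types were fixed before the data were examined and tested with camera (limma) at a preset correlation of 0.01, 2-sided, for lists with at least 5 tested members, with adjustment over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a set move on balance one way without comparing them with other genes, stand beside it. The named genes follow a rule also fixed then. It takes Pten, the 12 largest rises and the 12 largest falls among called genes that have a mean of at least 5 CPM in the higher group and no overlap between the groups (predicted gene models left out), up to 2 risen and 2 fallen members of each list with the largest changes, and a few genes of prior interest (Lgals9, Lox, Spp1, Ccl2, Csf1, Cd274, Akt1, Akt2 and Akt3). Genes outside it are said to have been chosen after their values were seen.

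Samples of a group were first compared with each other. The chi-square per degree of freedom between recovered reads of 2 samples of a group ran from 1.935 to 10.08, so no 2 libraries agreed within sampling noise and all were kept as separate samples. Alternatives planned beforehand were pseudocounts of 0.1 and 0.5, no filter and a minimum mean of 5 CPM, rescaling to equal sums, median-of-ratios scaling, quantile normalization, eBayes without a trend and robust eBayes (for the lists, camera without a variance trend and camera on the moderated statistics), a replicate block, leaving out each sample, and limma's treat test against a log2 change of 0.5. Tests on the recovered reads were added after the unit was known, with edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0.

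The scripts were tested on simulated data with the means and library sizes of these samples. Over 12468 genes with 200 changed, the limma test recovered 76% of 1.25-fold, 86% of 1.5-fold, 98% of 2-fold and 100% of 4-fold changes, with 8 false calls (4.26% of calls). In 100 simulated draws camera called an unchanged list in 0% and a raised list in 100%. Each gene was drawn independently and few were changed. These rates therefore do not cover lists with correlated members, nor data in which 49.9% of genes pass. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).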

Results

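RNA sequencing was used to measure gene expression in GL261 cells, a mouse glioma line, in which the tumour suppressor gene Pten had been targeted. A lentivirus carried a short hairpin RNA (shRNA, which lowers a target transcript by RNA interference) into the cells, and puromycin selection gave a stable line for each construct. The 6 samples fell into 2 groups of 3, the control line shNC and the knockdown line shPTEN. The reads recovered from the deposited values came to 21914772, 23573286 and 22106676 for shNC replicates 1, 2 and 3, and to 22357267, 21518371 and 18372943 for shPTEN replicates 1, 2 and 3. Between 21082 and 21766 genes had a value above 0 in a sample. Values are CPM (reads of a gene scaled to the sample's total), given as mean ± SD with n = 3 per group, and fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. The labels do not say whether the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. Each group was also a single stable line, so any difference between the 2 lines other than the knockdown enters every comparison.

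The targeted gene was examined first. Pten encodes the lipid phosphatase that opposes PI3K by removing a phosphate from PIP3, and lies on chromosome 19 from 32757497 to 32826160 on the plus strand (GRCm38, the assembly also called mm10). It stood at 158.1, 176.2 and 153.2 CPM in the shNC replicates and at 106.1, 113.2 and 110.4 CPM in the shPTEN replicates. The mean fell from 163 ± 12.1 to 109.9 ± 3.59 CPM, so that 67.6% of the control transcript level remained. The difference was larger than the spread between replicates, with a log2 fold change of -0.56 (SE 0.055, limma adjusted p = 1.23e-06). The exact permutation test gave p = 0.1, the smallest that 3 samples against 3 allow. Transcript level was measured here and protein level was not analysed. Of the genes for AKT, the kinase downstream of PI3K, Akt1 fell from 388 ± 6.94 to 321 ± 5.72 CPM (adjusted p = 5.92e-05) and Akt3 rose from 7.45 ± 1.28 to 10.9 ± 0.386 CPM (adjusted p = 0.00119). Akt2 rose by a small amount, from 151 ± 1.46 to 164 ± 0.751 CPM (adjusted p = 0.0333), and this call was lost under several settings, among them edgeR on the recovered reads (adjusted p = 0.062).

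**Figure D1:**
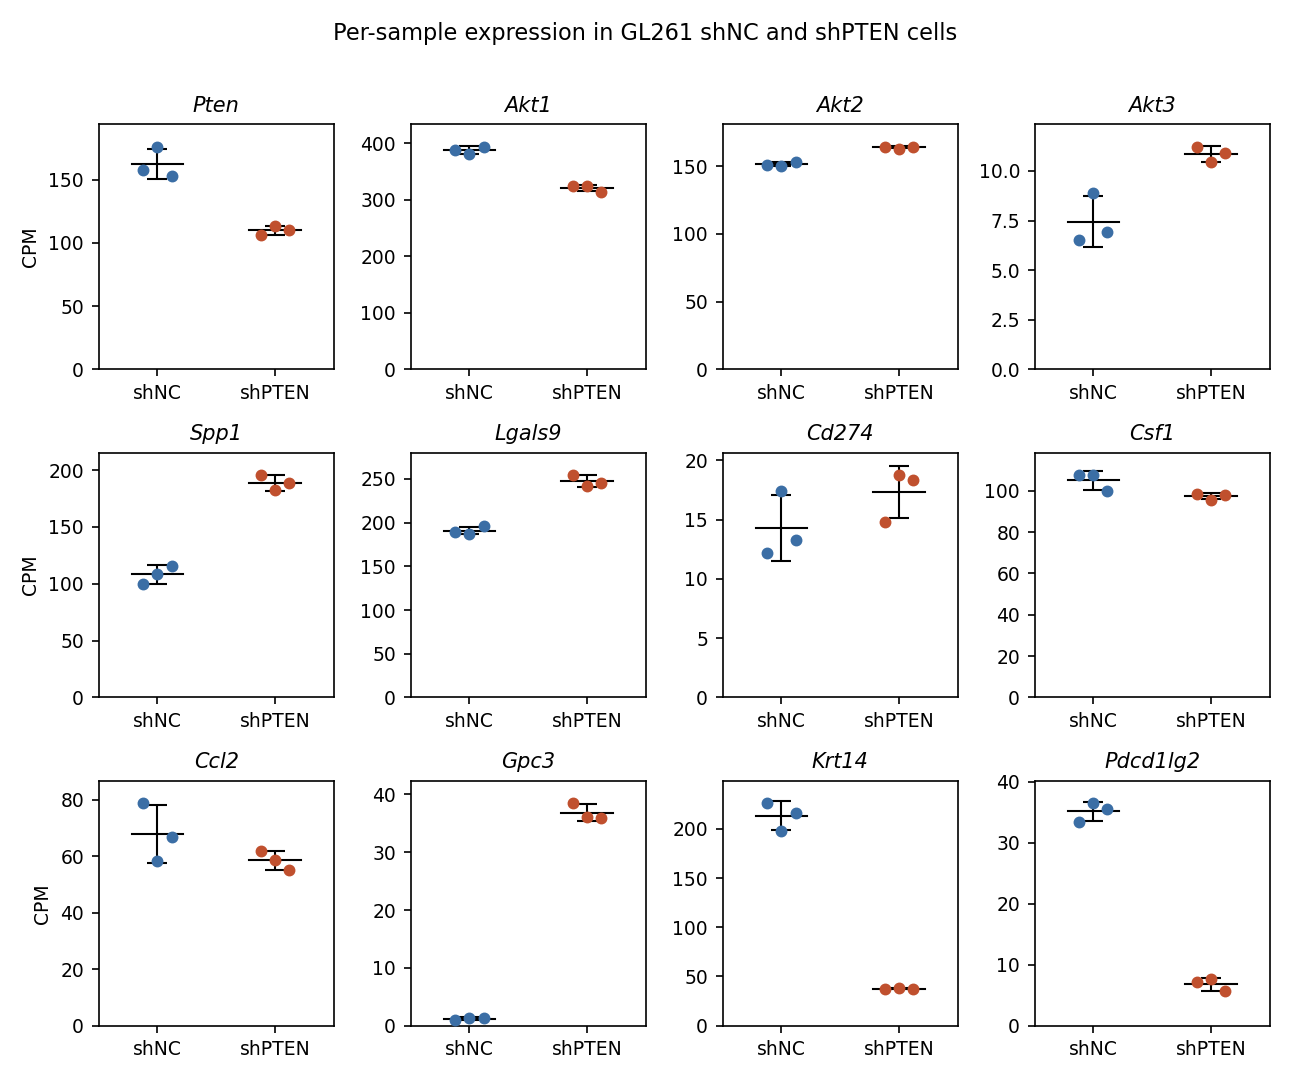
Expression in CPM (y axis, from 0) of 12 genes in the 3 shNC samples (blue) and the 3 shPTEN samples (orange). Each point is a sample, the horizontal line is the group mean and the bars are 1 SD. Pten, Akt1, Krt14 and Pdcd1lg2 were lower in all shPTEN samples, Spp1, Lgals9, Akt2, Akt3 and Gpc3 were higher in all of them, and the Cd274 and Ccl2 values of the groups overlapped.

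The comparison of shPTEN with shNC asks which transcripts differ once Pten is lowered in glioma cells. Of 12468 tested genes, 6219 passed the limma test at an adjusted p under 0.05 (49.9%), 3357 of them higher and 2862 lower in shPTEN. Most of the changes were small. The median absolute log2 fold change of the genes that passed was 0.34, and 1941 of them changed by less than 0.25 on the log2 scale. Changes of at least 2-fold were found for 382 genes that were higher and 110 that were lower. The higher count was 235 at a minimum mean of 5 CPM, and the lower count was 166 with a pseudocount of 0.1, 177 with edgeR and 179 with DESeq2. The values of the groups did not overlap for 7053 genes, 56.6% of those tested, where chance gives 10%. The first principal component held 84.95% of the variance and separated the groups. Against a minimum log2 change of 0.5, limma's treat test left 841 genes, and Pten itself was not among them (log2 fold change -0.56, close to that bound).

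**Figure D2:**
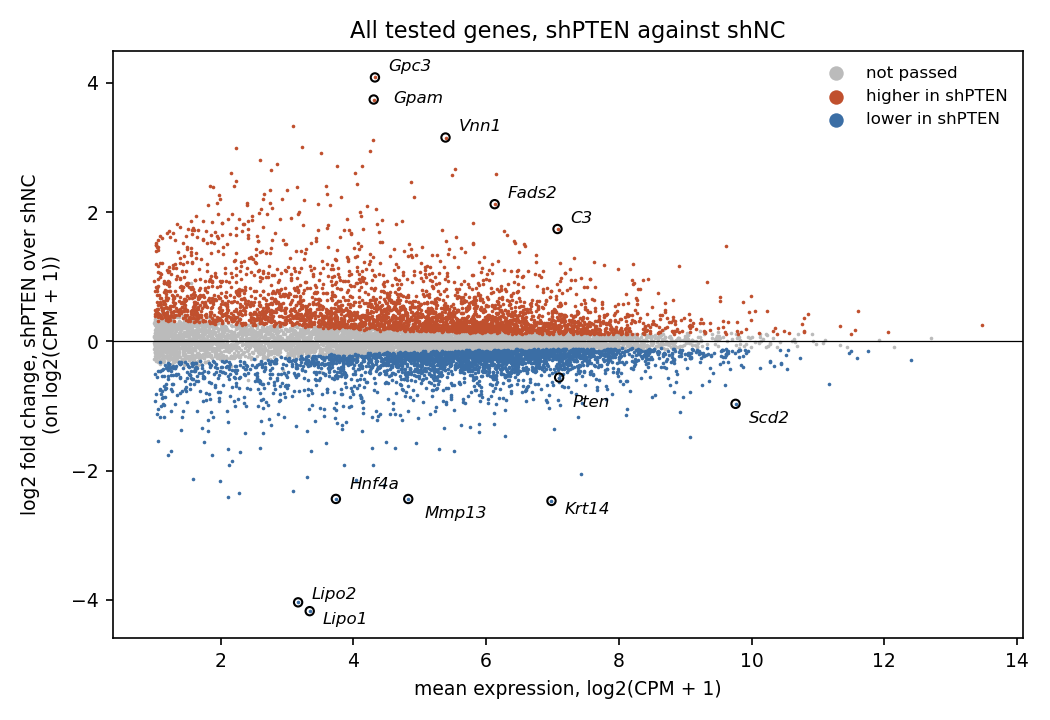
Log2 fold change of shPTEN over shNC (y axis) against mean expression as log2(CPM + 1) (x axis) for the 12468 tested genes. Orange points are the 3357 genes higher in shPTEN, blue points the 2862 lower ones and grey points those that did not pass the test. Gpc3 and Gpam lie highest, and Lipo1 and Lipo2 lie lowest, below -4 on the log2 scale.

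Among genes that passed with groups that did not overlap, a mean of at least 5 CPM in the higher group and no symbol of a predicted model or pseudogene, the 12 largest rises ran from 2.72 to 4.08 on the log2 scale. Gpc3, a cell-surface heparan sulfate proteoglycan, rose from 1.24 ± 0.244 to 36.8 ± 1.45 CPM, a log2 fold change of 4.08 (SE 0.0973, adjusted p = 1.42e-12). Gpam, the mitochondrial acyltransferase that starts glycerolipid synthesis, rose from 1.76 ± 0.426 to 35.8 ± 2.8 CPM (log2 fold change 3.74). Vnn1, a membrane-anchored pantetheinase, rose from 7.46 ± 0.706 to 74.3 ± 3.85 CPM (log2 fold change 3.16). Others encode enzymes of steroid or xenobiotic metabolism. Akr1c14, an aldo-keto reductase, rose from 3.07 ± 0.409 to 34.3 ± 2.65 CPM, and Gsta3, a glutathione S-transferase, from 1.07 ± 0.042 to 15.7 ± 1.07 CPM. Cyp11a1, which cleaves the side chain of cholesterol in steroid synthesis, rose from 0.522 ± 0.26 to 9.59 ± 0.492 CPM, and the flavin-containing monooxygenase Fmo1 from 3.65 ± 0.349 to 29.5 ± 0.978 CPM. The other 5 were Eef1d, which encodes a subunit of an elongation factor (0.532 ± 0.203 to 14.4 ± 1.2 CPM), the kinesin Kif1a (3.37 ± 0.412 to 32.6 ± 1.15 CPM), the sialomucin Podxl (1.68 ± 0.355 to 19.1 ± 1.69 CPM), the IFI200 family member Ifi203 (0.871 ± 0.165 to 11.6 ± 0.635 CPM) and the aldolase Aldoc (2.63 ± 1.06 to 22.2 ± 2.24 CPM). Their log2 fold changes ran from 2.72 for Aldoc to 3.34 for Eef1d. Akr1c14, Gsta3 and Ifi203 have close paralogs, Eef1d overlaps Naprt on the same strand, and the strand setting of the counting is not given in the sources used here, so reads shared with related or overlapping genes leave their levels uncertain.

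By the same rule the 12 largest falls ran from -2.10 to -4.17 on the log2 scale. Lipo1 and Lipo2, neighbouring members of the lipase family, went from 18.2 ± 1.35 to 0.0635 ± 0.0229 CPM and from 15.9 ± 1.1 to 0.0304 ± 0.0263 CPM, with log2 fold changes of -4.17 and -4.04. Summed over the 3 samples of a group, Lipo1 had 1233 reads in shNC and 4 in shPTEN, a ratio of 0.00348 after scaling to depth (95% interval 0.000958 to 0.00904, exact Clopper-Pearson on the split of reads). Lipo2 had 1079 and 2 reads, a ratio of 0.00191 (95% interval 0.000243 to 0.00729). Such intervals cover counting error only. Krt14, a keratin of basal epithelial cells, fell from 214 ± 14.4 to 37.7 ± 0.317 CPM (log2 fold change -2.47, adjusted p = 1.42e-12), and the collagenase gene Mmp13 from 46.9 ± 6.55 to 7.84 ± 1.21 CPM. The transcription factor genes Hnf4a and Lmx1a fell from 21.5 ± 2.02 to 3.15 ± 0.263 CPM and from 6.23 ± 0.588 to 0.373 ± 0.191 CPM. Pdcd1lg2, which encodes a ligand of the checkpoint receptor PD-1, fell from 35.1 ± 1.54 to 6.78 ± 1.04 CPM (log2 fold change -2.22). The others of the 12 were Lmcd1 (7.07 ± 0.943 to 0.579 ± 0.0206 CPM), Tmem179 (13.2 ± 0.929 to 1.87 ± 0.366 CPM), the neuronal adhesion molecule Nrcam (5.48 ± 0.564 to 0.458 ± 0.125 CPM), Glrp1 (25.9 ± 0.576 to 5.1 ± 0.177 CPM) and the synaptotagmin Syt13 (14.9 ± 2.04 to 2.69 ± 0.122 CPM).

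Lipo1 and Lipo2 lie on chromosome 19 on the same side of Pten, on the minus strand, from 33775498 to 33787459 and from 33719670 to 33751359. The other genes between Pten and Stambpl1 were examined after these values had been seen. Those with group means summing to over 0.1 CPM all had few reads in shNC and fewer in shPTEN. Rnls had 28 and 5 reads, Lipo4 15 and 0, Lipo3 8 and 2, Gm8978 30 and 0, Lipk 28 and 3, and Lipn 106 and 10 in the respective groups. The ratio of Lipn was 0.105 (95% interval 0.0477 to 0.196), and the interval of Lipo3 included 1 (0.0281 to 1.36). On the far side, Stambpl1 fell with a log2 fold change of -0.68 (adjusted p = 9.63e-08), and Fas and Slc16a12 rose by 0.29 and 1.82 on the log2 scale. Upstream of Pten the genes were mixed. Minpp1, Asah2 and Sgms1 fell with log2 fold changes of -0.45 (adjusted p = 2.54e-06), -0.45 (adjusted p = 0.000117) and -0.21 (adjusted p = 0.00655), Papss2 rose by 0.53 (adjusted p = 0.000591), and Atad1 had a log2 fold change of 0.10 that did not pass (adjusted p = 0.0822). Lipo3 overlaps Lipo2 and Gm8978 on the same strand, so the assignment of their reads is uncertain.

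**Figure D3:**
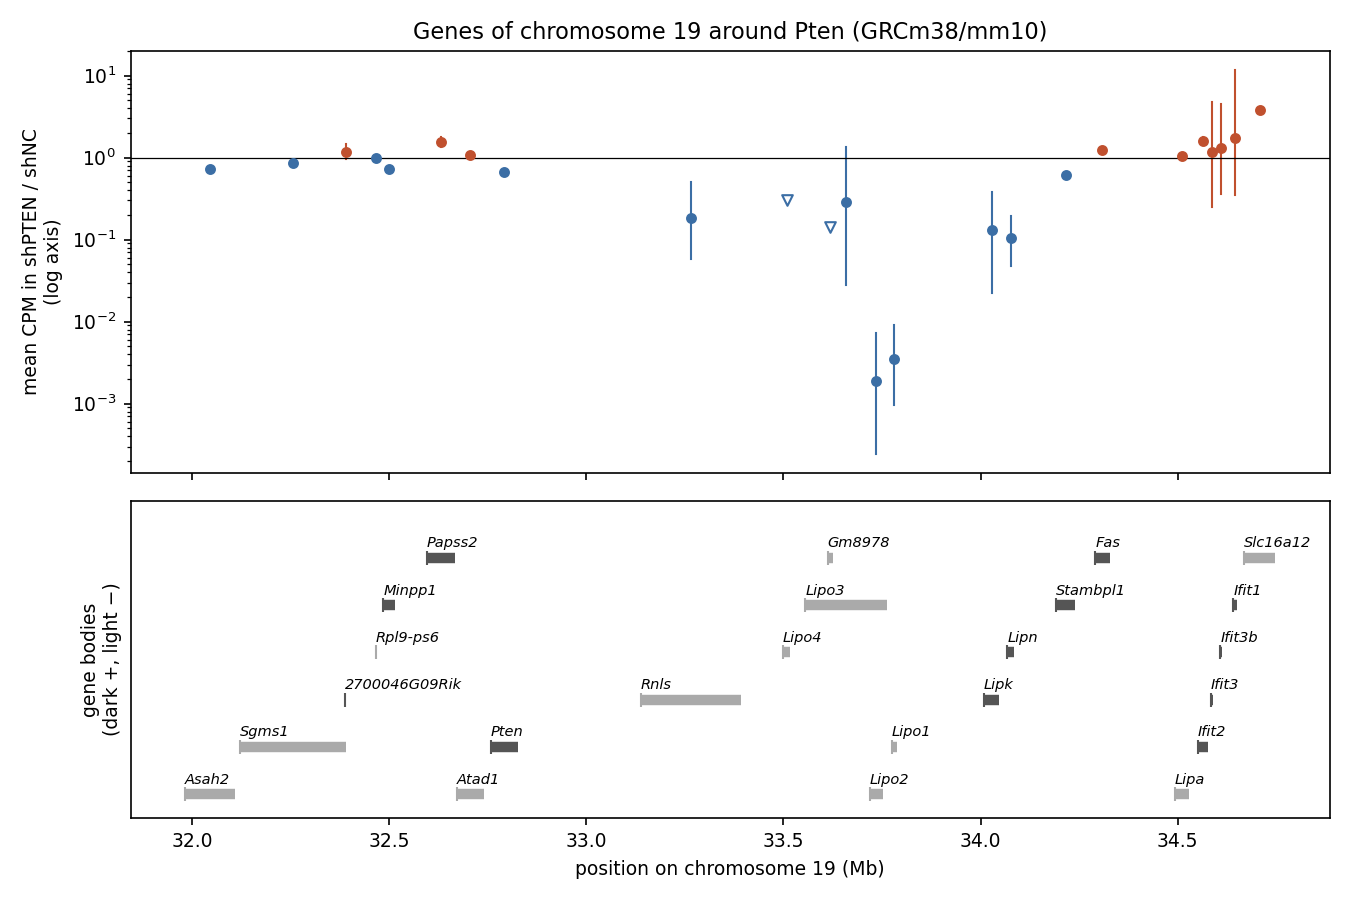
Genes of chromosome 19 around Pten. The upper panel gives the ratio of the mean CPM in shPTEN to that in shNC (log axis) at each gene's midpoint, with a 95% exact counting interval, and open triangles mark the upper bound for genes with 0 reads in shPTEN. The lower panel shows gene bodies by position in Mb on GRCm38, limited to genes whose 2 group means sum to over 0.1 CPM. Lipo1 and Lipo2 have ratios of 0.00348 and 0.00191, and Pten and Stambpl1, on either side of them, have ratios of 0.676 and 0.621.

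Genes were next grouped by 30 lists fixed before the data were examined, of which 28 had at least 5 tested members. With camera at a preset correlation of 0.01, 15 lists passed at an adjusted p under 0.05, 11 higher and 4 lower in shPTEN. With an estimated correlation camera called 0 lists (lowest adjusted p = 0.0942), 5 had an unadjusted p under 0.05, and fry called 23. Each camera call below was thus made with the preset correlation only. Camera asks whether a list moved more than the other genes, and fry whether its members moved on balance. Where fry called a list that camera did not, its adjusted p is given. Counts of members are over all genes tested, with those adjusted over the list alone in parentheses.

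**Figure D4:**
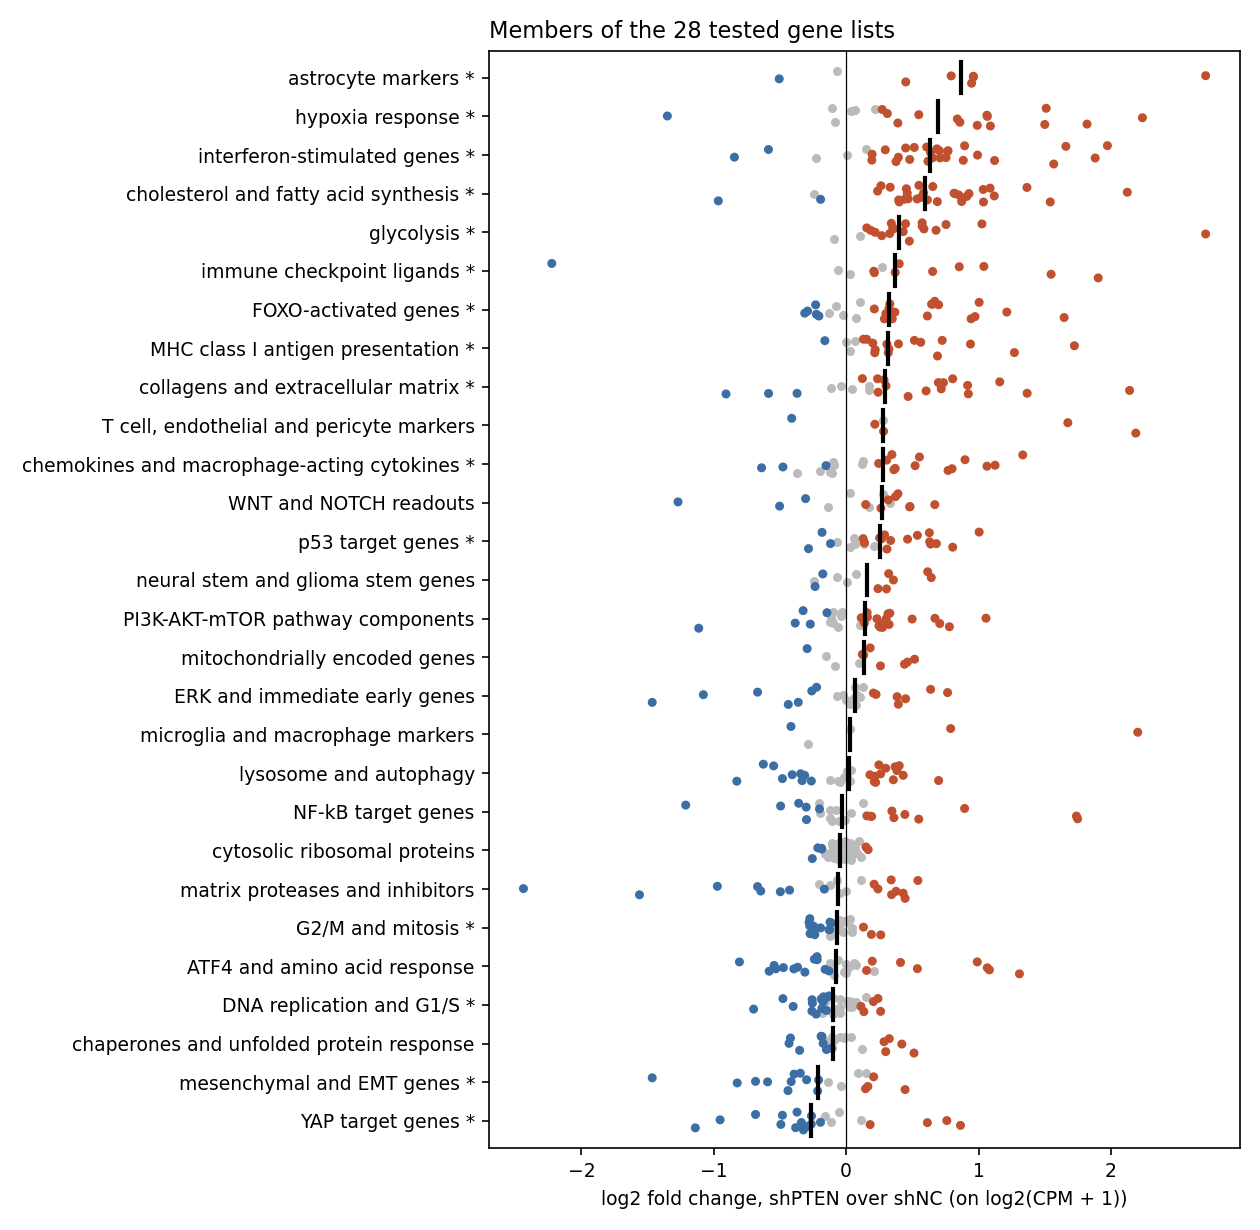
Log2 fold change of shPTEN over shNC (x axis) for each tested member of the 28 lists (rows, ordered by median), with small random vertical offsets. Orange and blue points are members that rose or fell at an adjusted p under 0.05, grey points did not pass, black bars are medians and asterisks mark the 15 lists called by camera with the preset correlation. The members of the cholesterol, glycolysis, hypoxia and interferon lists lie mostly to the right of 0, and ribosomal protein genes cluster around 0.

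Genes of cholesterol and fatty acid synthesis rose together. Of 32 tested members 29 rose and 2 fell (29 and 3 adjusted over the list alone), with a median log2 fold change of 0.60 (camera adjusted p = 1.5e-11, adjusted p = 0.228 with an estimated correlation). Fads2, a fatty acid desaturase, rose from 25.1 ± 1.43 to 113 ± 6.6 CPM, and Dhcr7, which catalyses the last step of cholesterol synthesis, from 9.86 ± 0.55 to 30.6 ± 1.13 CPM. The stearoyl-CoA desaturase gene Scd2 fell from 1145 ± 79.6 to 585 ± 20.5 CPM (adjusted p = 1.96e-09). Fasn, the fatty acid synthase, fell from 409 ± 34.1 to 357 ± 13.7 CPM (adjusted p = 0.0105), a call lost without shPTEN replicate 1 (adjusted p = 0.0516) and without a variance trend (adjusted p = 0.0583). Glycolysis genes rose as well. Of 20 tested members 18 rose and 0 fell (18 and 0 adjusted over the list alone), and the median was 0.40 (camera adjusted p = 3.98e-07, adjusted p = 0.228 with an estimated correlation). Aldoc led this list, and Pfkm, the muscle form of phosphofructokinase, rose from 35.5 ± 0.659 to 73.3 ± 1.56 CPM. In the hypoxia response list, 14 of 20 tested members rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 4.86e-06, adjusted p = 0.345 with an estimated correlation). Bnip3, a mitophagy receptor, rose from 9.67 ± 2.62 to 48.3 ± 3.62 CPM and Ankrd37 from 1.24 ± 0.321 to 6.85 ± 0.421 CPM, whereas Stc1, which encodes a secreted glycoprotein, fell from 187 ± 13.3 to 72.5 ± 3.81 CPM.

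Components of the PI3K, AKT and mTOR pathway were not called by camera against other genes but were called higher by fry. Of 33 tested members 18 rose and 5 fell (19 and 6 adjusted over the list alone) (camera adjusted p = 0.229, fry adjusted p = 0.0373). Deptor, an inhibitor that binds mTOR, rose from 24.5 ± 1.82 to 52 ± 1.6 CPM, and Pik3cd, a catalytic subunit of PI3K, from 0.723 ± 0.249 to 1.95 ± 0.321 CPM. Akt1s1, which encodes the mTOR complex inhibitor PRAS40, fell from 94.4 ± 7.07 to 43 ± 2.08 CPM, and the AKT-activating kinase gene Pdpk1 from 58.9 ± 7.22 to 44.7 ± 3.51 CPM. Targets activated by FOXO transcription factors, which AKT holds outside the nucleus, were higher in shPTEN. Of 28 tested members 18 rose and 5 fell (18 and 5 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00109, adjusted p = 0.345 with an estimated correlation). Pdk4, an inhibitor of pyruvate dehydrogenase, rose from 1.59 ± 0.214 to 7.1 ± 0.541 CPM and Txnip, which restrains glucose uptake, from 82.8 ± 5.98 to 193 ± 0.887 CPM. Klf2 fell from 116 ± 19.1 to 92.5 ± 1.17 CPM. The p53 target list was also higher. Of 25 tested members 15 rose and 3 fell (17 and 3 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00105, adjusted p = 0.228 with an estimated correlation). Sesn1, which belongs to the FOXO list too, rose from 10.7 ± 0.896 to 22.5 ± 0.614 CPM and Zmat3 from 83.3 ± 1.81 to 146 ± 3.02 CPM. The nuclease gene Aen fell from 123 ± 7.09 to 108 ± 0.649 CPM and Rrm2b from 38.3 ± 4.78 to 31.2 ± 2.3 CPM, the latter not passing without shPTEN replicate 3 (adjusted p = 0.0521).

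Interferon-stimulated genes were higher in shPTEN. Of 31 tested members 26 rose and 2 fell (26 and 2 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 4.2e-07, adjusted p = 0.0942 with an estimated correlation). Oasl2, a member of the oligoadenylate synthetase family, rose from 1.64 ± 0.156 to 9.39 ± 1.04 CPM and the GTPase gene Iigp1 from 1.38 ± 0.196 to 7.75 ± 0.359 CPM. Oasl1 and the exonuclease gene Isg20 fell, from 85.2 ± 1.52 to 47 ± 0.827 CPM and from 11.8 ± 0.526 to 7.55 ± 0.231 CPM. For MHC class I antigen presentation, 16 of 20 tested members rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.000165, adjusted p = 0.228 with an estimated correlation). The immunoproteasome subunit genes Psmb8 and Psmb9 rose from 0.47 ± 0.16 to 3.85 ± 0.367 CPM and from 0.900 ± 0.19 to 3.62 ± 0.842 CPM. H2-T22 fell from 54.6 ± 3.95 to 48.7 ± 1.98 CPM (adjusted p = 0.0445), a call lost when any of 5 samples was left out, with adjusted p up to 0.174, and also without a filter on low values (0.0851), without a variance trend (0.0853) and with a replicate block (0.0528). H2 and Oasl genes have close paralogs, so reads counted for related genes leave their levels uncertain. Immune checkpoint ligands were higher as a list. Of 13 tested members 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.00297, adjusted p = 0.228 with an estimated correlation). Cd80, which encodes a ligand of CD28 and CTLA-4, rose from 2.51 ± 0.455 to 12.1 ± 1.6 CPM and Vtcn1 from 4.52 ± 0.359 to 15.1 ± 0.637 CPM, and the member that fell was Pdcd1lg2. Lgals9, which encodes galectin-9, rose from 191 ± 4.48 to 247 ± 6.83 CPM (log2 fold change 0.37, adjusted p = 5.98e-06). Cd274, the gene for PD-L1, stood at 14.3 ± 2.77 CPM in shNC and 17.3 ± 2.18 CPM in shPTEN and did not pass (adjusted p = 0.0741), although it passed with a replicate block (adjusted p = 0.0158), without shNC replicate 2 (adjusted p = 0.00141) and without shPTEN replicate 1 (adjusted p = 0.0226).

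Among chemokines and macrophage-acting cytokines, 13 of 24 tested members rose and 3 fell (14 and 4 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0294, adjusted p = 0.498 with an estimated correlation). The camera call was lost without a filter on low values (adjusted p = 0.204), without a variance trend (adjusted p = 0.0592) and without shNC replicate 2 (adjusted p = 0.0811). Cx3cl1, the membrane-bound chemokine fractalkine, rose from 60.4 ± 1.35 to 154 ± 6.25 CPM and the cytokine gene Il18 from 10.5 ± 1.17 to 24.1 ± 1.26 CPM. Spp1, which encodes osteopontin, rose from 108 ± 7.95 to 189 ± 6.83 CPM (log2 fold change 0.80, adjusted p = 3.12e-08). Lif and Tgfb1 fell, from 38.6 ± 3.62 to 24.4 ± 1.247 CPM and from 123 ± 3.13 to 87.9 ± 0.856 CPM. Ccl2, a chemokine that attracts monocytes, stood at 67.9 ± 10.3 CPM in shNC and 58.6 ± 3.33 CPM in shPTEN (adjusted p = 0.0662) and Csf1, the growth factor of macrophages, at 105 ± 4.46 CPM in shNC and 97.3 ± 1.39 CPM in shPTEN (adjusted p = 0.075), so that neither difference passed. Both passed, as lower in shPTEN, under edgeR on the recovered reads (adjusted p = 0.0461 and 0.0403) and median-of-ratios scaling (adjusted p = 0.0477 and 0.038). Ccl2 also passed under DESeq2 (adjusted p = 0.0291), with a replicate block (adjusted p = 0.0193) and without shNC replicate 2 (adjusted p = 0.000653), and Csf1 without shNC replicate 3 (adjusted p = 0.0255). Lox, also a gene of prior interest, was not among the genes of the main test, so no value is given for it. For NF-kB targets, 10 of 27 tested members rose and 6 fell (10 and 6 adjusted over the list alone) (camera adjusted p = 0.906, called higher by fry with adjusted p = 0.00785). Within that list the complement gene C3 rose from 61.1 ± 1.01 to 207 ± 8.09 CPM and Lcn2 from 0.371 ± 0.0779 to 3.62 ± 0.446 CPM, while Traf1 fell from 3.89 ± 0.166 to 1.11 ± 0.16 CPM and Relb from 45 ± 2.52 to 31.6 ± 0.778 CPM. Of the microglia and macrophage markers, measured beside these groups, 2 of 5 tested members rose and 1 fell (2 and 1 adjusted over the list alone), a list that camera did not call (adjusted p = 0.698) and fry called higher (adjusted p = 0.0258). Lyz2 rose from 0.358 ± 0.101 to 5.55 ± 2.64 CPM and Csf1r from 0.964 ± 0.284 to 2.39 ± 0.473 CPM, and Cd68 fell from 9.12 ± 0.721 to 6.58 ± 0.565 CPM.

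Targets of the YAP coactivator and mesenchymal genes were lower in shPTEN. For YAP targets, 4 of 21 tested members rose and 13 fell (4 and 13 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.00314, adjusted p = 0.301 with an estimated correlation). Igfbp3 fell from 377 ± 7.52 to 171 ± 1.9 CPM and Ankrd1 from 228 ± 3.03 to 118 ± 3.02 CPM, while the kinase gene Nuak2 rose from 24.7 ± 1.46 to 45.7 ± 0.648 CPM and F3, which encodes tissue factor, from 8.47 ± 0.353 to 15.1 ± 1.33 CPM. In the mesenchymal and EMT list (epithelial to mesenchymal transition), 4 of 19 tested members rose and 11 fell (4 and 11 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.0101, adjusted p = 0.228 with an estimated correlation). The transcription factor gene Fosl1 fell from 114 ± 4.95 to 40.6 ± 0.358 CPM and the hyaluronan receptor gene Cd44 from 478 ± 21.9 to 269.8 ± 2.39 CPM. Serpine1 rose from 208 ± 25.4 to 283 ± 15.1 CPM and Stat3 from 122 ± 8.72 to 141 ± 7.51 CPM. Collagens and extracellular matrix genes went the other way. Of 24 tested members 16 rose and 3 fell (17 and 4 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.00314, adjusted p = 0.301 with an estimated correlation). Col12a1 rose from 0.951 ± 0.184 to 7.62 ± 0.994 CPM and the laminin gene Lamb1 from 4.38 ± 0.635 to 12.8 ± 0.896 CPM, and Col8a1 and Col18a1 fell, from 176 ± 12.9 to 93.3 ± 2.88 CPM and from 82.7 ± 2.93 to 54.7 ± 1.96 CPM. Matrix proteases and their inhibitors were split, as 8 of 22 tested members rose and 8 fell (8 and 8 adjusted over the list alone) (camera adjusted p = 0.229, called lower by fry with adjusted p = 0.0125). Mmp13 and Mmp10 fell, the latter from 32.6 ± 5.51 to 10.3 ± 1.39 CPM, and Mmp19 rose from 0.978 ± 0.078 to 1.89 ± 0.318 CPM.

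Cell cycle genes shifted by small amounts. In the DNA replication and G1/S list, 5 of 37 tested members rose and 14 fell (6 and 14 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.0294, adjusted p = 0.498 with an estimated correlation). Dhfr, dihydrofolate reductase, fell from 121 ± 6.44 to 74.1 ± 3.39 CPM and the histone mRNA binding protein gene Slbp from 67.2 ± 2.61 to 48 ± 2.98 CPM. Of the G2/M and mitosis genes, 3 of 30 tested members rose and 12 fell (3 and 12 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0294, adjusted p = 0.345 with an estimated correlation). The kinetochore gene Ndc80 fell from 62.6 ± 2.06 to 51.4 ± 1.92 CPM and the kinesin gene Kif2c from 139.5 ± 2.83 to 115 ± 2.01 CPM, and Bub1 rose from 64.1 ± 1.6 to 77 ± 1.42 CPM. Both camera calls were lost at a minimum mean of 5 CPM (adjusted p = 0.0567 for G1/S and 0.0527 for G2/M), under quantile normalization (0.144 and 0.173) and without shNC replicate 1 (0.0734 and 0.0505). The G2/M call was also lost without shNC replicate 2 (adjusted p = 0.0552).

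Other pathways had members that changed without a camera call. In the ATF4 and amino acid response list, 8 of 32 tested members rose and 13 fell (8 and 14 adjusted over the list alone) (camera adjusted p = 0.306), with Cebpb rising from 8.71 ± 4.07 to 21.9 ± 3.95 CPM, Gpt2 rising from 10.2 ± 1.03 to 22.8 ± 0.894 CPM and Nupr1 falling from 13.6 ± 0.804 to 7.36 ± 0.208 CPM. For ERK and immediate early genes, 7 of 24 tested members rose and 7 fell (7 and 7 adjusted over the list alone) (camera adjusted p = 0.906, called lower by fry with adjusted p = 0.0443). Spry1, a feedback inhibitor of receptor tyrosine kinase signalling, rose from 64.3 ± 1.52 to 110.2 ± 6.5 CPM, and Fosb fell from 4.84 ± 0.793 to 1.75 ± 0.136 CPM. In the lysosome and autophagy list, 13 of 30 tested members rose and 9 fell (13 and 10 adjusted over the list alone) (camera adjusted p = 0.906), with Gabarapl1 rising from 62 ± 3.36 to 101 ± 4.69 CPM and Atg5 falling from 38.6 ± 2.09 to 21.3 ± 0.882 CPM. Of the WNT and NOTCH readouts, 8 of 16 tested members rose and 3 fell (9 and 3 adjusted over the list alone) (camera adjusted p = 0.212, called higher by fry with adjusted p = 0.0464). Znrf3, a ubiquitin ligase that restrains WNT signalling, rose from 55.7 ± 3.17 to 89.2 ± 5.41 CPM and the receptor gene Lgr5 from 152 ± 12.7 to 213 ± 10.6 CPM, while the ligand gene Wnt5a fell from 97.2 ± 10.9 to 39.7 ± 3.75 CPM and the transcription factor gene Tcf7 from 88.2 ± 4.22 to 61.9 ± 2.39 CPM. Chaperones and genes of the unfolded protein response were mixed, as 5 of 22 tested members rose and 8 fell (5 and 8 adjusted over the list alone) (camera adjusted p = 0.369), with Herpud1 rising from 58.7 ± 1.74 to 84.1 ± 1.92 CPM and Manf falling from 97.5 ± 14.7 to 71.5 ± 2.78 CPM. Ribosomal protein genes were close to level, as 2 of 43 tested members rose and 4 fell (0 and 3 adjusted over the list alone) and the median was -0.04 (camera adjusted p = 0.298). Without shNC replicate 2 that list was called (adjusted p = 0.00623). The median, mean and camera direction differed in sign for 4 lists, those of ATF4, NF-kB, ERK and lysosome genes.

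Markers of neural and other cell types were measured in the same way. Of the astrocyte markers, 6 of 8 tested members rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 0.00326, adjusted p = 0.301 with an estimated correlation). Glul, glutamine synthetase, rose from 234 ± 2.58 to 457 ± 4.44 CPM, Aldoc belongs to this list too, and the connexin gene Gja1 fell from 103 ± 6.85 to 72 ± 2.67 CPM. Of the neural stem and glioma stem genes, 6 of 12 tested members rose and 2 fell (6 and 2 adjusted over the list alone) (camera adjusted p = 0.256, called higher by fry with adjusted p = 0.00379), with Sox9 rising from 48.2 ± 0.995 to 74.4 ± 3.06 CPM and Ezh2 falling from 116 ± 5.28 to 103 ± 1.85 CPM. For T cell, endothelial and pericyte markers, 4 of 6 tested members rose and 1 fell (4 and 1 adjusted over the list alone) (camera adjusted p = 0.0521, called higher by fry with adjusted p = 0.000101). This list passed camera under several settings, with adjusted p from 0.0423 without shNC replicate 1 to 0.0496 without shNC replicate 2. Kcnj8 and Des, which pericytes and muscle cells express, rose from 2.47 ± 0.747 to 14.6 ± 0.557 CPM and from 2.39 ± 0.301 to 9.79 ± 0.256 CPM. The oligodendrocyte list had 2 tested members, Pdgfra at 15.6 ± 1.41 CPM in shNC and 16.5 ± 1.09 CPM in shPTEN and Plp1 at 2.25 ± 0.381 CPM in shNC and 2.07 ± 0.264 CPM in shPTEN, and neither passed. The neuron list had 1, the vesicular glutamate transporter gene Slc17a6, which fell from 5.85 ± 0.379 to 0.84 ± 0.323 CPM. Of the mitochondrially encoded genes, 7 of 11 tested members rose and 1 fell (7 and 1 adjusted over the list alone) (camera adjusted p = 0.177), with mt-Nd6 rising from 176 ± 11.2 to 253 ± 34.9 CPM and mt-Nd1 falling from 5974 ± 163 to 4869 ± 94.9 CPM. Under quantile normalization the mt-Nd1 call was lost, with a log2 fold change of -1.606e-15. That method gives equal ranks equal values, so a gene that keeps its rank shows no change there. The loss thus does not bear on whether mt-Nd1 fell. All rows with a symbol starting in mt-, tested or not, held 2.41% to 2.60% of reads in the shNC samples. They held 2.68% to 2.72% in the shPTEN samples.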

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

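The tests on recovered reads were chosen after the data had been examined, and the other settings before. The count of 6219 changed genes lay between 5040 and 6634 when each sample was left out, was 6251 with edgeR (6012 of them shared) and 5642 with DESeq2 (5546 shared), and in no setting did a gene called in both carry the opposite sign. The share of higher genes among those called was 54.0% as reported, 46.1% under quantile normalization, 50.5% with edgeR and 49.8% with DESeq2. Rescaling to equal sums changes nothing by construction, since the columns already sum alike. The treat test against 0.5 left 841 genes, 598 higher and 243 lower, and did not call Pten (-0.5583), since it asks for changes beyond that bound. In all other settings Pten was called, with log2 fold changes from -0.5993 to -0.499. The count of genes at least 2-fold higher was 235 at a minimum mean of 5 CPM, which tests fewer genes, and 525, 525 and 526 with a pseudocount of 0.1, edgeR and DESeq2. The count at least 2-fold lower rose to 166 with a pseudocount of 0.1, 177 with edgeR and 179 with DESeq2, since a smaller pseudocount or a count model pulls low genes less toward 0.

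The replicate numbers did not pair the samples. Correlations of the deviations of same-numbered samples were 0.135, 0.0639 and -0.214, and a fit with the number as a replicate block called 6105 genes, 5989 of them shared. Camera called 15 lists as reported and 13 to 16 in the other settings that kept the preset correlation. It called 0 with an estimated correlation, and fry, which asks another question, called 23. The estimated correlation was -0.017 for the interferon list, which was still not called with it (adjusted p = 0.0942). For the other lists called as reported it ran from 0.0205 (mesenchymal genes) to 0.493 (hypoxia response). Members that move together thus do not account for every lost call. Over 132 named genes, alternatives left the call as it was in 2353 cases, ended it in 124 and added one in 11, and over 28 lists in 490, 25 and 15 cases. No direction was reversed. At these depths a gene at the minimum mean of 1 CPM rests on 18.4 to 23.6 reads per sample, so depth limits mainly the low genes.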

Other observations

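The gene families in the next paragraph were chosen after the gene table had been seen. So were the test of chromosome medians and the comparison of the Lipo1 and Lipn ratios. The NRF2 median without Gstm1 and Gsta4 was also read afterwards, as were the chi-square values set beside the spread within groups. These tests therefore describe these samples and are no independent evidence. The other tests below were written down before their results were seen.

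Ligands of the EGF receptor family were lower in shPTEN. Of 7 tested members 5 fell and 0 rose at an adjusted p under 0.05, with a median log2 fold change of -0.59 (camera adjusted p = 0.00184 over 7 lists, adjusted p = 0.139 with an estimated correlation). Areg, the gene of amphiregulin, fell from 14.8 to 3.88 CPM, Btc from 5.58 to 1.07 CPM, Tgfa from 135 to 72.3 CPM and Hbegf from 121 to 80.2 CPM. Families of enzymes that modify steroids and foreign compounds were higher. Among glutathione S-transferases 9 of 16 rose and 2 fell (median 0.37, camera adjusted p = 0.00819, adjusted p = 0.372 with an estimated correlation), led by Gsta3 and by Gstt1, which rose from 0.873 to 10.7 CPM. Of 17 cytochrome P450 genes 8 rose and 2 fell (camera adjusted p = 0.0259, adjusted p = 0.203 with an estimated correlation), with Cyp7b1 rising from 1.249 to 9.25 CPM and Cyp1a1 falling from 157 to 97.7 CPM. Of 12 aldo-keto reductases 7 rose and 3 fell (camera adjusted p = 0.0259, adjusted p = 0.256 with an estimated correlation). All 3 UDP-glucuronosyltransferases rose, Ugt2b35 from 7.92 to 48.3 CPM, as did 2 of 3 flavin-containing monooxygenases. In a pooled list of the PHF11 and IFI200 families 5 of 9 rose and 4 fell (camera adjusted p = 0.585), and all those that fell were IFI200 members. Keratins split, with 6 of 16 rising and 6 falling (camera adjusted p = 0.585), as Krt5 rose from 7.66 to 20.3 CPM while its usual partner Krt14 fell. No family was called with an estimated correlation. Close paralogs in these families can share reads, which was not tested for them.

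A hypothesis for the detoxifying enzymes was activation of NRF2, the transcription factor of the oxidative stress response. On 27 tested core targets the median log2 fold change was 0.112, between the 0.3 that was set for activation and the 0.1 set against it (limma camera p = 0.05, adjusted p = 0.07, adjusted p = 0.216 with an estimated correlation). In that list 14 genes rose, Nqo1 from 6.37 to 15.9 CPM among them, and 3 fell, Slc7a11 from 60.2 to 48.2 CPM among them, while Hmox1 stood at 48.6 and 49.99 CPM and Txnrd1 at 290.2 and 281 CPM. Gstm1 and Gsta4, which rose by 1.38 and 1.80 on the log2 scale, are in this list and also in the families that prompted the hypothesis. Both lie above the list median, which would be lower without them. Without them the middle value of the list is that of Hmox1, 0.037, which is under the 0.1 set against activation. As written beforehand, the list leaves the hypothesis open. Its median exceeds 0.1 only with these members of the families to be explained.

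Of the tested genes 6219 of 12468 passed, while 67.6% of the Pten transcript remained, and how many genes such a fall would change was not tested. A scaling difference between the groups as the source of most calls is argued against. Limma called 6287 genes under median-of-ratios scaling (6030 shared with the main test) and 6279 under quantile normalization (5585 shared). With TMM edgeR, which changes the test as well, called 6251 (6012 shared). The share of higher genes among those called did depend on scaling, at 54% as reported and 46.1% under quantile normalization. A further explanation is that libraries of a group vary little more than counting noise. The shared biological coefficient of variation was 0.0499, which just met the bound of under 0.05 set beforehand for it. The chi-square per degree of freedom reached 10.08 between shNC libraries and 3.821 between shPTEN libraries, so the libraries did vary beyond counting noise. That measure grows with the number of reads, so it does not contradict a small coefficient. The coefficient thus goes with the explanation, by a margin too narrow to settle it, and the explanation stays open. Of the 10 splits of the 6 samples into 3 and 3, 1 gave as many genes, the real one, and the highest other split gave 0 in limma (713 at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05. Whether the changes come from lower Pten or from other differences between the stable lines cannot be tested with 1 line per group.

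Lipo1 and Lipo2 were near 0 in shPTEN, and their neighbours toward Pten and Stambpl1 were low. Reads moved to paralogs are argued against, since the other Lipo genes gained -0.94% of the CPM lost. Loss of a DNA segment in the shPTEN line stays open. The lower log2 ratio of the nearest expressed genes of other families was -0.688, for Stambpl1, between the bounds of -0.8 and -0.5 set beforehand, and the gene on the other side was Pten itself (-0.565), which the shRNA targets. The ratios of Lipo1 and Lipn, 0.00348 and 0.105, have counting intervals that do not overlap. They cannot decide on a segment that spans both genes, since they rest on 4 and 10 reads in shPTEN. Where reads that few come from is not known. Silencing of the locus in this line or through Pten was not tested.

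Gains or losses of chromosomes in a line could shift many genes at once. A change of whole chromosomes in most cells is argued against. The highest absolute chromosome median of the log2 fold change was 0.0876, for chromosome 6. A change from 4 copies to 5 in most cells gives about 0.3. The share of genes higher in shPTEN still differed between chromosomes, from 39.3% on chromosome 19 to 64.4% on chromosome 6. For segments, the highest median over 40 neighbouring genes was 0.248, on chromosome 1 from 75307896 to 86278284, and 71 of 1000 shuffles of gene order reached as much. The bound of 0.15 set beforehand against this explanation was too low, as the median of the shuffles was 0.207. Over windows of 40 neighbouring genes a shared shift was therefore not shown. The shares of higher genes on whole chromosomes were not set against shuffles, so this result does not cover them. Segments shorter than 40 genes, and changes of segments or whole chromosomes in part of the cells, stay open.

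FOXO-activated genes were higher in the line with less Pten, with 18 of 28 tested members rising and 5 falling (camera adjusted p = 0.00109, adjusted p = 0.345 with an estimated correlation), although AKT, which Pten restrains, keeps FOXO factors out of the nucleus. Where this difference comes from was not tested.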
